A study of Bos taurus with 24 samples.

How the data were processed

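RNA of bovine granulosa cells was sequenced in 24 libraries: 4 of granulosa cells from secondary follicles (secondary_GC), 5 each of cumulus cells (early_CC) and mural granulosa cells (early_MGC) from early antral follicles, and 5 each of the same cell types from late antral follicles (late_CC and late_MGC). Granulosa cells are the somatic cells around the oocyte; cumulus cells are those next to it and mural cells line the follicle wall. The labels give total RNA, a low-input cDNA kit and transposase-based libraries. They do not say whether the replicates came from separate animals or cultures, so every p-value here measures only the spread between these samples.

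The deposited table holds counts of reads per gene, which per the file headers the authors made with featureCounts 2.0.0 on the exons of an Ensembl annotation of the ARS-UCD1.2 genome, without options for strand, read pairs or reads with several alignments. The submitters' processing notes list fastp 0.20.0, HISAT2 2.1.0 and SAMtools 1.10 before that step, and the build bosTau9. The values are whole numbers for 27607 genes, of which 6590 had no count in any library. The deposited table also gives the summed exon length of each gene in bases, which served only to look for length trends. Because counting ignored strand, antisense and overlapping transcripts cannot be separated, and genes of multigene families (histones, globins and the major histocompatibility gene BOLA-DQB1) may share reads.

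Total counts ran from 8379801 to 31762400 per library, with a median of 18070281.5. A gene with no count in a group was given a limit of 3 counts over that group, between 0.0244 and 0.0402 CPM (counts divided by the library's total, times 1000000). Such limits cover counting error only, since the reads carry no molecular identifiers. A further column of undetermined reads, 41567882 counts or 8.3% of all counts in the table, belongs to no sample and entered no test. The 5 column names of late_MGC carry no replicate number and the numbers of the 4 secondary_GC columns differ from those of the sample titles, so libraries of these 2 groups are numbered here by column order. No 2 libraries of a group were copies of each other: the lowest chi-square per degree of freedom over the 46 pairs within groups was 17.4.

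Symbols were assigned by position. The gene identifiers of the table were matched to the RefSeq annotation of the next assembly version, ARS-UCD2.0, where each of a pair of gene spans was the other's best match with an overlap of at least 0.5 of their union, or where start and end were identical. On each autosome and X, 24.3% to 48.0% of genes had an identical end in both annotations, against at most 0.13% after a shift of 1000 bases, and 37 of 37 mitochondrial genes did. Of the 12219 genes with a mean of at least 1 CPM, 10761 (88.1%) received a symbol, and 93.9% of all counts fell in genes with one. After a shift of 1000000 bases, 952 of these 12219 genes would still have been given a symbol, so a single name can be wrong. Of the 194 genes the naming rule selects, 65 share an identical start or end and the lowest overlap of the others was 0.509.

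Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter, robust dispersions and all 24 libraries in 1 fit by group. It tested 14298 genes, and a gene was called where its Benjamini-Hochberg adjusted p was under 0.05. Standard errors (SE) of log2 fold changes are those implied by the test statistic. The biological coefficient of variation was 42.4%. The 6 comparisons are early_MGC and early_CC against secondary_GC, late_MGC against early_MGC, late_CC against early_CC, and early_CC against early_MGC and late_CC against late_MGC. A 7th test took the interaction of stage and cell type over the 4 antral groups, and the calls of separate comparisons were then overlapped. Simulated data had the fitted dispersions and, per comparison, 100 genes changed 2-fold and 100 changed 4-fold. There the 6 comparisons recovered 24% to 38% of genes changed 2-fold and 76% to 85% of genes changed 4-fold. The interaction recovered 11% and 69%. False calls made up 1.6% to 7.6% of the simulated calls. The 6 simulated comparisons called 112 to 126 genes, against 285 to 6457 in the real data. The cut on p set by the adjustment loosens with more calls, so recovery in the larger comparisons was not measured.

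The comparisons, the tests, 17 gene lists, the naming rule and the alternatives were fixed before the data were examined. The lists cover granulosa maturation and steroidogenesis, filopodia and actin protrusions, gap and adherens junctions, BMP and TGF-beta receptors and response, cumulus expansion and EGF-like ligands, cell cycle, cholesterol biosynthesis and uptake, glycolysis, basement membrane, YAP and TEAD targets, the Notch pathway, apoptosis and p53 response, immediate early and heat shock genes, and markers of oocytes, theca and stroma, endothelium and blood cells. Each list was tested in each of the 6 comparisons with camera of limma 3.58.1 on the edgeR fit, with a preset correlation of 0.01 between genes, and adjusted over the 102 tests. All list tests were repeated with a correlation estimated from the data. Counts of members called over all genes are given beside those adjusted over the list alone. Summed CPM of the 4 marker lists, the mitochondrial share, the share of the 10 most abundant genes, genes detected and total counts were compared by exact two-sided permutation tests, adjusted over 48 tests.

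The naming rule selected, per comparison, the 6 genes with the largest rise and the 6 with the largest fall among called genes with a symbol, a mean of at least 10 CPM over the libraries and no overlap between the CPM of the 2 groups. It added up to 2 called members per direction of each list, some of which are left out of the text for length, and 11 genes whatever their result: FSHR, LHCGR, CYP19A1, AMH, GJA1, GJA4, MYO10, FSCN1, DAAM1, CDH1 and CDH2. For the interaction it selected the 4 largest values per direction without the overlap condition. For genes highest or lowest in early_MGC it selected 6 each by the smaller of the 2 changes, 1 of which is not used here.

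The alternatives fixed beforehand were the DESeq2 1.42.0 Wald test, median-of-ratios (RLE) scaling, no filter, a mean of at least 10 CPM, limma-voom with library weights, only the groups compared in the fit, a replicate block, each library left out in turn, at least a doubling or halving for the overlaps, an estimated correlation for the lists and TMM-scaled CPM for the marker sums. Chosen only after seeing the data were a fit without the 3 libraries that stand apart (late_MGC 3, late_CC 3 and early_MGC 4), a fit with offsets corrected for a trend of each library on exon length, drawn with a lowess span of 0.3, and a block by the well letter in the column names where these lack the numbers of the labels. Principal components used log2 CPM with a prior count of 2. Other splits of the libraries, 100 per result with the real one included, were refitted in the same way. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.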

Results

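Gene expression was measured in 24 libraries of bovine granulosa cells from secondary, early antral and late antral follicles. The study asks whether granulosa cells at different stages can regrow transzonal projections, the thin processes by which they contact the oocyte, and whether gene expression changes at the same stages. There were 4 libraries of secondary_GC and 5 of each of the antral groups early_CC, early_MGC, late_CC and late_MGC, with total counts between 8379801 and 31762400. Levels are CPM as mean ± SD over the 4 or 5 libraries of a group, and log2 fold changes are given with their SE and the adjusted p of edgeR's quasi-likelihood test. The principal component with the most variance held 30.02% of it and the next 14.7%. The gonadotrophin receptor FSHR stood at 260 to 359 CPM in every group on average. The luteinising hormone receptor LHCGR had 0 counts in secondary_GC, a limit of 0.0402 CPM. It averaged at most 0.0892 CPM elsewhere and was too low to test. Genes named as the largest rises and falls of a comparison were chosen for CPM that did not overlap between the 2 groups, so the lack of overlap is no separate support. The size of such a change can still rest on 1 library. SGK1, for example, stood at 658.5 CPM in late_MGC 3 against a mean of 1.36 in the other 4 late_MGC libraries. Replicates 3 of late_MGC and late_CC and replicate 4 of early_MGC, here the 3 libraries that stand apart, had the lowest mean correlation with their own group (0.870, 0.9145 and 0.9205). The next was close, secondary_GC 2 at 0.9225, and it was kept. Fits without the 3 were chosen after the data were examined, as were those with length-corrected offsets.

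**Figure D1:**
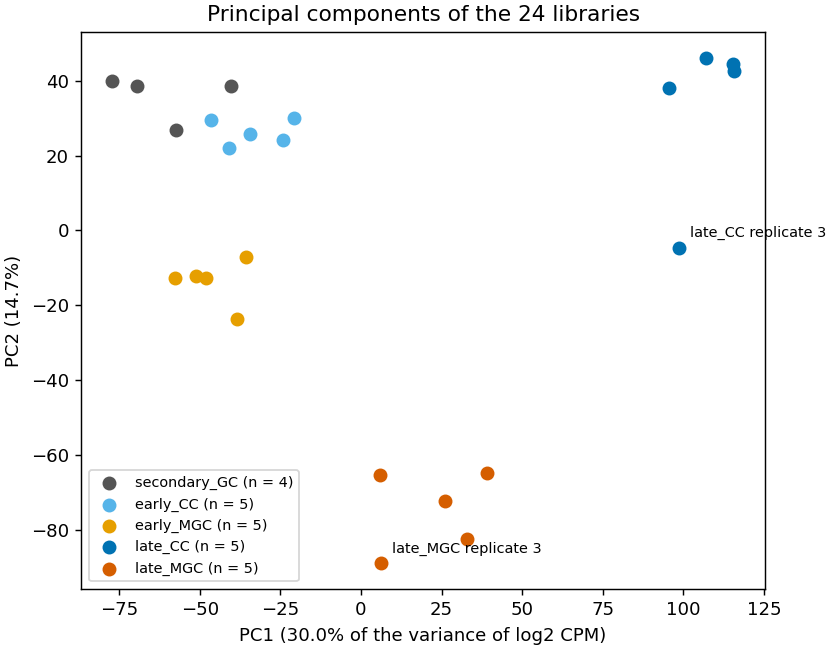
Principal components of log2 CPM over the 24 libraries, with the share of variance on each axis and colours for the 5 groups. On these axes PC1 holds 30.02% and PC2 14.7% of the variance, and replicates 3 of late_MGC and late_CC are marked.

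Between secondary_GC and early_MGC, which sets mural cells of the stage used as the reference for regrowing projections against cells of the preceding stage, 8 of 18 glycolysis genes fell and the BMP antagonist GREM1 rose. NDUFA4L2, which lowers the activity of respiratory complex I (ENSBTAG00000031503, chromosome 5, 56205859 to 56208161 in ARS-UCD1.2), fell from 27.6 ± 18.9 to 1.14 ± 0.963 CPM, a log2 fold change of -4.43 ± 1.002 (adjusted p = 0.010). CYP11A1, the enzyme that starts steroid synthesis from cholesterol (ENSBTAG00000006934, chromosome 21, 34328403 to 34342900), fell from 58.0 ± 27.4 to 13.5 ± 5.75 CPM (-1.96 ± 0.41, adjusted p = 0.0053). GREM1, a secreted antagonist of bone morphogenetic proteins (ENSBTAG00000050495, chromosome 10, 29964364 to 29978686), rose from 20.01 ± 2.71 to 87.2 ± 30.1 CPM (2.24 ± 0.25, adjusted p = 1.6e-05). In all, 1301 of 14298 genes were called, 717 higher and 584 lower in early_MGC, of which 354 and 335 changed at least 2-fold.

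The other largest rises were those of the histones H2AC13 (4.53 ± 0.50), H1-2 (2.63 ± 0.34) and H2BC18 (2.41 ± 0.45), the tRNA ligase complex member FAM98B (2.64 ± 0.28) and MSL2 (2.06 ± 0.36), part of a histone acetyltransferase complex. The largest falls included the cell surface protein NRXN2 (-4.91 ± 0.81), the embryonic globin HBZ (-3.37 ± 1.05), the lactate exporter SLC16A3 (-2.80 ± 0.70), the mitophagy receptor BNIP3 (-2.63 ± 0.60) and IER3 (-2.21 ± 0.63). Glycolysis genes fell as a list (8 of 18 fell and none rose, 15 fell adjusted over the list alone, adjusted p = 3.4e-09), among them PFKL (-1.71 ± 0.40) and GPI (-1.27 ± 0.31). The adjusted p = 0.74 with an estimated correlation. Notch pathway genes fell (4 of 14, none rose; adjusted over the list alone 4 fell and 1 rose; adjusted p = 0.043), with HES1 at -1.85 ± 0.45, and their adjusted p = 0.74 with an estimated correlation. BMP and TGF-beta genes rose (2 of 18, the same number adjusted over the list alone, adjusted p = 0.040), and for them too the adjusted p = 0.74 with an estimated correlation. Single members of uncalled lists rose, such as the membrane-actin linker RDX (0.72 ± 0.15), the actin nucleation subunit ARPC3 (1.15 ± 0.24) and the adhesion protein NECTIN3 (1.33 ± 0.25). None of the 10 tested genes fixed by name was called. Among them were the filopodial motor MYO10 (-0.37 ± 0.26), the actin bundler FSCN1 (-1.40 ± 0.93), the formin DAAM1 (-0.02 ± 0.31) and the gap junction proteins GJA1 (0.59 ± 0.30) and GJA4 (-1.43 ± 0.98). The others were CDH1 (0.39 ± 0.73), CDH2 (0.37 ± 0.27), FSHR (-0.10 ± 0.49), CYP19A1 (1.25 ± 0.71) and AMH (-0.25 ± 0.61). Summed oocyte markers were lower in early_MGC, at 12.96 ± 2.91 against 27.9 ± 5.99 CPM (exact two-sided permutation test, adjusted p = 0.0381).

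Without secondary_GC 4, 2, 1 or early_MGC 4 the count of calls in early_MGC against secondary_GC was 516, 850, 808 or 861. The call of HBZ was lost without any library other than secondary_GC 3 or early_MGC 2 (adjusted p = 0.0626 to 0.120). That of IER3 was lost without secondary_GC 2 or 4 or early_MGC 1, 3 or 4 (0.0562 to 0.181), and that of HES1 without secondary_GC 4 (-1.70, adjusted p = 0.0521). The BMP list was not called without secondary_GC 1 or 4 or early_MGC 5 (0.108, 0.056 and 0.102). The Notch list was not called without secondary_GC 2 or 3 or early_MGC 1 or 3 (0.177, 0.0644, 0.116 and 0.068) or with RLE scaling (0.0537). Without filtering, HBZ and IER3 were not called (0.0837 and 0.0613), nor HBZ with limma-voom (0.282) and IER3 with length-corrected offsets (0.0639). Without the 3 libraries that stand apart, of which early_MGC 4 is 1, FSCN1 was called at -1.57 (adjusted p = 0.0227), GJA4 at -1.65 (0.0246) and CYP19A1 at 1.34 (0.000625). The 3 were also called with the 2 groups alone (-1.40, 0.0297; -1.43, 0.0361; 1.26, 0.0212), and FSCN1 and GJA4 with limma-voom (-1.63, 0.00699 and -1.68, 0.00717).

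Early cumulus cells differed least from secondary_GC, a comparison that asks what the cells next to the oocyte gain or lose as the antrum forms. GREM1 rose to 58.5 ± 10.7 from 20.01 ± 2.71 CPM (1.58 ± 0.25, adjusted p = 0.0011). CPE, a peptidase of prohormone processing, fell to 20.96 ± 7.95 from 93.0 ± 15.1 CPM (-2.13 ± 0.33, adjusted p = 0.0011). The vesicle exocytosis gene CADPS2 rose (3.20 ± 0.50), as did the protease inhibitor WFDC2 (5.18 ± 1.15), the metalloprotease MEP1B (5.17 ± 1.03), CAPN6 (3.96 ± 0.66), TMEM156 (3.75 ± 0.88) and CPXM1 (2.83 ± 0.58). The adhesion receptor VCAM1 (-4.37 ± 1.07), the secreted protein MSMB (-3.34 ± 0.55), the mRNA decay factor ZFP36L1 (-2.83 ± 0.54), IFRD1 (-2.34 ± 0.59), the growth factor binding protein IGFBP6 (-2.12 ± 0.52) and the stress response gene SESN1 (-1.46 ± 0.27) fell. The test called 285 genes, 135 higher and 150 lower, of which 99 and 140 changed at least 2-fold.

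Cell cycle genes lay higher as a list in early_CC than in secondary_GC, although none of the 29 was called alone and 1 rose adjusted over the list alone (adjusted p = 0.00032). Its adjusted p = 0.81 with an estimated correlation. Cholesterol genes lay higher too, with 0 of 22 called and 0 adjusted over the list alone (adjusted p = 0.020). The list's adjusted p = 0.84 with an estimated correlation. YAP and TEAD targets lay lower (1 of 16 fell, 3 adjusted over the list alone, adjusted p = 0.027). The list's adjusted p = 0.79 with an estimated correlation. The immediate early and heat shock list lay lower, although its only called member rose (1 of 25; adjusted over the list alone 2 rose and 4 fell; adjusted p = 0.042). The list's adjusted p = 0.88 with an estimated correlation. Blood cell markers lay lower (0 of 7 called, 2 fell adjusted over the list alone, adjusted p = 0.013). The list's adjusted p = 0.57 with an estimated correlation. Their summed level was 6.69 ± 2.31 CPM in early_CC and 37.02 ± 9.26 in secondary_GC (exact two-sided permutation test, adjusted p = 0.0381). Summed endothelial markers were 21.8 ± 6.47 against 33.3 ± 4.002 CPM (exact test, adjusted p = 0.0476). Again none of the 10 tested genes fixed by name was called. MYO10 stood at -0.10 ± 0.26, FSCN1 at -2.25 ± 0.94, DAAM1 at -0.23 ± 0.31, GJA1 at 0.13 ± 0.30, GJA4 at -1.43 ± 0.97, CDH1 at 1.64 ± 0.74, CDH2 at 0.33 ± 0.26, FSHR at 0.18 ± 0.49, CYP19A1 at 0.89 ± 0.70 and AMH at 0.52 ± 0.61.

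The count of calls in early_CC against secondary_GC was 150, 160, 151, 182, 173 and 157 without secondary_GC 2, secondary_GC 4 or early_CC 1, 2, 3 or 4. It was 1304 without the 3 libraries that stand apart, none of which is in these groups. In that fit FSCN1 (-2.25, adjusted p = 0.0014), GJA4 (-1.44, 0.0424), CDH1 (1.64, 0.000217) and CYP19A1 (0.90, 0.014) were called. FSCN1, GJA4 and CDH1 were also called with limma-voom (-2.17, 0.000345; -1.58, 0.00452; 1.42, 0.0266) and with the 2 groups alone (-2.30, 0.0015; -1.48, 0.0417; 1.59, 0.00541). DESeq2, limma-voom with library weights, a fit of the 2 groups alone, length-corrected offsets and a mean of at least 10 CPM gave 722, 812, 964, 432 and 148. Leaving out 1 library ended the calls of WFDC2 (secondary_GC 2, 3 or 4, adjusted p = 0.0552 to 0.0795), TMEM156 (secondary_GC 1, 2 or 3 or early_CC 1 or 4, 0.0509 to 0.0863) and VCAM1 (any but secondary_GC 1, 0.0603 to 0.0892). It also ended those of IFRD1 (any but secondary_GC 1 or 3, 0.0777 to 0.244, with -1.43 without secondary_GC 2) and IGFBP6 (any but early_CC 5, 0.0502 to 0.0881). Without filtering, TMEM156, VCAM1, IFRD1 and IGFBP6 were not called either (0.0554, 0.0637, 0.0804 and 0.0641), nor IFRD1 with limma-voom (0.0502). The cholesterol list lost its call without secondary_GC 3 (0.133) and the YAP list without secondary_GC 2 (0.142). The immediate early list lost it without secondary_GC 1 or 4 or early_CC 1 or 3 (0.110, 0.141, 0.124 and 0.0877) and with RLE scaling (0.0616).

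From early to late antral follicles, the stages between which the study tests mural cells for loss of projection growth, HSD3B1 and CYP11A1 rose in mural cells, and NKD1 and GREM1 fell. HSD3B1, which makes progesterone (ENSBTAG00000006769, chromosome 3, 23706733 to 23717051), rose from 11.5 ± 4.64 to 141 ± 93.8 CPM (3.66 ± 0.48, adjusted p = 1.6e-05). CYP11A1 rose from 13.5 ± 5.75 to 123 ± 73.6 CPM (3.25 ± 0.42, adjusted p = 1.1e-05). NKD1, a feedback inhibitor of Wnt signalling (ENSBTAG00000012295, chromosome 18, 18940443 to 19034788), fell from 21.2 ± 6.83 to 0.175 ± 0.208 CPM (-6.87 ± 0.59, adjusted p = 2.7e-08). GREM1 fell from 87.2 ± 30.1 to 15.98 ± 4.84 CPM (-2.33 ± 0.23, adjusted p = 2.9e-07). MYO10, a motor that carries cargo to the tips of filopodia (ENSBTAG00000020126, chromosome 20, 56233771 to 56495596), fell from 41.5 ± 7.56 to 18.7 ± 6.21 CPM (-1.08 ± 0.25, adjusted p = 0.0041). The test called 2725 genes, 1396 higher and 1329 lower, of which 522 and 1041 changed at least 2-fold.

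Other large rises in late_MGC were those of the growth factor receptor PDGFRA (5.36 ± 1.19), the potassium channel KCNN1 (4.43 ± 0.73), DKK3 (3.68 ± 0.42), the matrix protein POSTN (3.57 ± 0.60) and the fatty acid binding protein FABP3 (3.42 ± 0.50). EXOC3L1 (-6.25 ± 0.46), the lectin COLEC11 (-5.62 ± 0.59), CAPN6 (-5.48 ± 0.71), C11H2orf92 (-5.24 ± 0.50) and the major histocompatibility gene BOLA-DQB1 (-6.58 ± 1.59), whose reads may be shared within its family, fell most. Granulosa maturation genes rose as a list (10 of 24 rose and 1 fell, 12 and 1 adjusted over the list alone, adjusted p = 0.0012), and the member that fell was the AMH receptor AMHR2 (-3.26 ± 0.46). The adjusted p = 0.74 with an estimated correlation. Immediate early and heat shock genes fell (11 of 25, 1 rose, the same numbers adjusted over the list alone, adjusted p = 0.00051), and this list's adjusted p = 0.79 with an estimated correlation. Among them were the transcription factors JUN (-1.96 ± 0.41) and JUND (-1.41 ± 0.28). Cholesterol genes rose (5 of 22, none fell, the same adjusted over the list alone, adjusted p = 0.038), and their adjusted p = 0.90 with an estimated correlation. So did cell cycle genes (2 of 29, none fell, 0 adjusted over the list alone, adjusted p = 0.023). The list's adjusted p = 0.97 with an estimated correlation. Members of uncalled lists that fell were the prostaglandin synthase PTGES (-3.48 ± 0.59), the BMP response gene ID1 (-2.69 ± 0.57) and the Notch target HEYL (-3.73 ± 0.53), while the membrane linker EZR (0.91 ± 0.21) and the junction protein CTNNB1 (0.73 ± 0.17) rose. Among the genes fixed by name GJA1 (0.82 ± 0.28, adjusted p = 0.045) and the cadherin CDH1 (2.47 ± 0.70, adjusted p = 0.017) also rose. FSHR (0.21 ± 0.46), CYP19A1 (0.64 ± 0.65), AMH (0.02 ± 0.57), GJA4 (-0.54 ± 0.94), FSCN1 (0.67 ± 0.88), DAAM1 (0.49 ± 0.29) and CDH2 (0.00 ± 0.25) were not called. Summed oocyte markers were 4.44 ± 1.22 CPM in late_MGC and 12.96 ± 2.91 in early_MGC (exact two-sided permutation test, adjusted p = 0.0381). Endothelial markers, led by FLT1, stood at 9.27 ± 10.7 against 38.1 ± 9.28 CPM (exact test, adjusted p = 0.0476).

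Library late_MGC 3 stood far from the other 4 late_MGC libraries, with 10.6 CPM of FSHR against 335 ± 36.4 and 276 CPM of the matrix protein DCN against 2.90 ± 0.672. Without it, FSCN1 was called lower in late_MGC (-2.69, adjusted p = 0.000437), as was GJA4 (-4.03, 0.000157), and FSHR was called higher (0.52, 0.0424). CDH1 was then not called (0.19, 0.648), and PDGFRA and POSTN stood at 1.84 and 2.27. GJA1 was not called without any library other than early_MGC 4 or late_MGC 3 (adjusted p = 0.0586 to 0.121), with RLE scaling (0.063), in a fit of the 2 groups alone (0.182) or over genes of at least 10 CPM (0.0878). Without the 3 libraries that stand apart it was called at 1.32 (6.5e-05), and so was CYP19A1 (0.87, 0.0068). The cell cycle list lost its call without early_MGC 4 or 5 or late_MGC 1, 4 or 5 (0.0786, 0.156, 0.175, 0.109 and 0.0585). The cholesterol list lost it without early_MGC 4 or 5 or late_MGC 1, 2, 4 or 5 (0.115, 0.0675, 0.120, 0.064, 0.061 and 0.102). BOLA-DQB1 was not called with limma-voom (0.298), nor PDGFRA (0.115, and 0.0612 in a fit of the 2 groups alone). CDH1 was called neither with limma-voom (0.29, 0.547) nor in the fit of the 2 groups (0.141), while FSCN1 (-2.94, 0.000359) and GJA4 (-3.77, 0.000111) were called with limma-voom. The total was 4756 with limma-voom, 1608 over genes of at least 10 CPM and 1612 with the 2 groups alone.

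**Figure D2:**
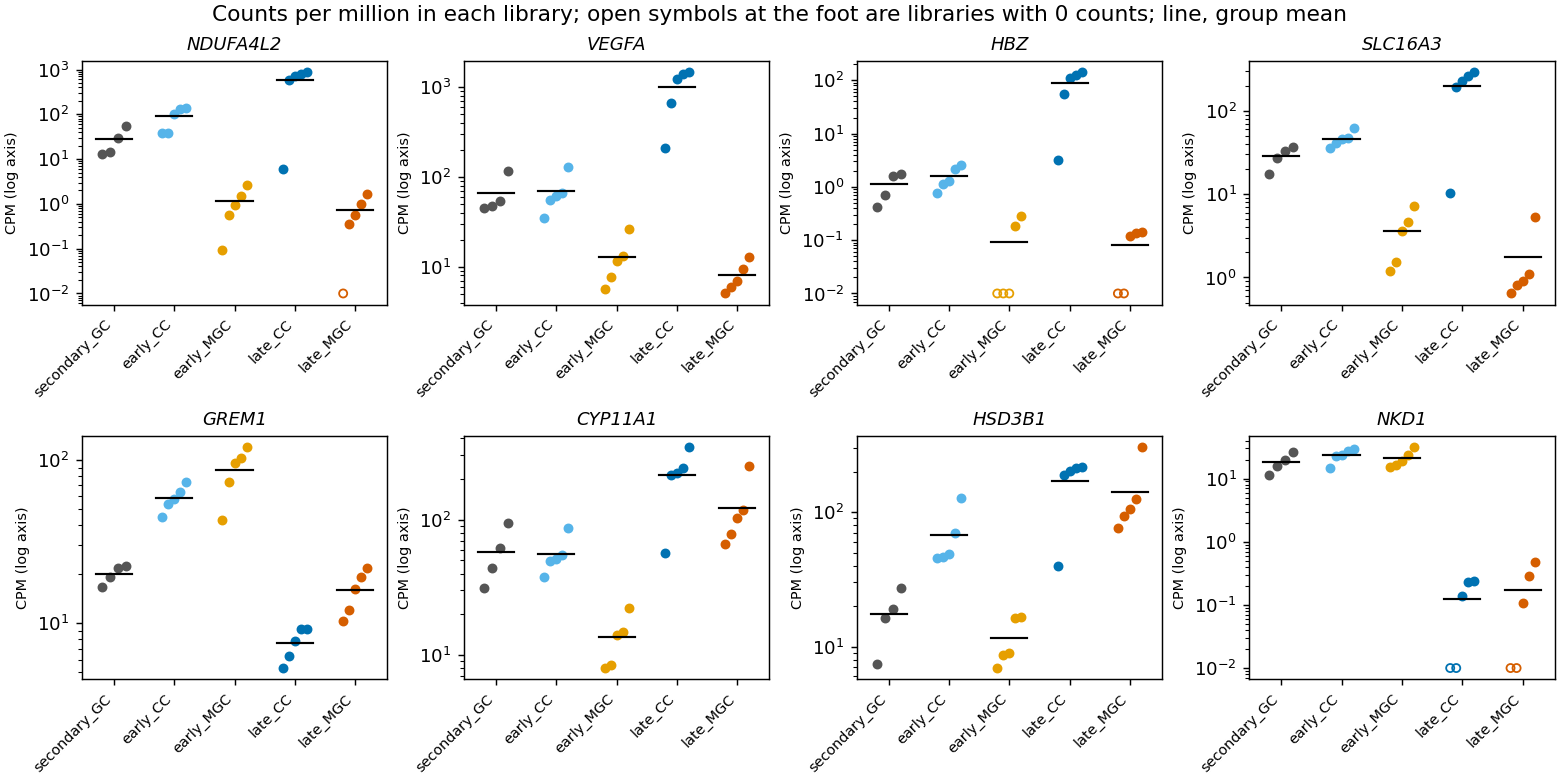
CPM of 8 genes in each of the 24 libraries on log axes, with a line at each group mean and open symbols for libraries with 0 counts. NDUFA4L2 averaged 593 CPM in late_CC and 0.726 CPM in late_MGC, and GREM1 averaged 87.2 CPM in early_MGC, the highest of its 5 group means.

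Cumulus cells changed most of all between early and late antral follicles: 26 of 29 cell cycle genes fell and the globins HBZ and HBA rose. HBZ (ENSBTAG00000038921, chromosome 25, 198487 to 199498) rose from 1.58 ± 0.741 to 87.7 ± 57.3 CPM (5.77 ± 0.72, adjusted p = 2.7e-06). The adult-type alpha globin HBA rose from 0.123 ± 0.0262 to 43.1 ± 28.1 CPM (8.38 ± 0.98), and members of this family can share reads. NKD1 fell from 23.6 ± 5.76 to 0.122 ± 0.118 CPM (-7.52 ± 0.62, adjusted p = 6.7e-09), and GREM1 from 58.5 ± 10.7 to 7.55 ± 1.74 CPM (-2.95 ± 0.24). GJA4, the gap junction protein connexin 37 (ENSBTAG00000013881, chromosome 3, 110888198 to 110890904), fell from 3.78 ± 1.62 to 0.157 ± 0.243 CPM (-4.55 ± 1.18, adjusted p = 0.0034). The formin DAAM1 rose from 22.6 ± 4.02 to 58.7 ± 14.9 CPM (1.39 ± 0.30, adjusted p = 0.00050). The test called 6457 genes, 3210 higher and 3247 lower in late_CC, of which 1960 and 2307 changed at least 2-fold.

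The kinase RIPK4 (6.11 ± 0.77), the adaptor SKAP2 (5.23 ± 0.56), the oxygen sensor EGLN3 (4.90 ± 0.73), IGFBP4 (4.83 ± 0.85) and the inhibin subunit INHBB (4.08 ± 0.56) rose most beside HBZ. Beside NKD1, the largest falls were those of the cadherin CDH13 (-6.69 ± 0.54), the transcription factor KLF4 (-6.61 ± 1.33), DCN (-6.02 ± 1.44), the inositol synthase ISYNA1 (-5.80 ± 0.39) and the growth factor PDGFB (-5.76 ± 1.11). Of 29 cell cycle genes 26 fell and 1 rose, the same numbers adjusted over the list alone (adjusted p = 3.4e-09), with the kinase CDK1 at -2.22 ± 0.30 and the cyclin CCND2 as the member that rose (1.45 ± 0.34). The adjusted p = 0.74 with an estimated correlation. Granulosa maturation genes rose (11 of 24, 1 fell, the same adjusted over the list alone, adjusted p = 0.020), and their adjusted p = 0.79 with an estimated correlation. They were led by NR5A2 (2.1 ± 0.29), a nuclear receptor of the steroidogenic programme. Lists without a call still held changed members, such as HK2 (1.73 ± 0.36) and SLC2A1 (1.68 ± 0.45) of glycolysis, and HES1 (3.27 ± 0.44), DLL4 (2.04 ± 0.48) and HEYL (-5.35 ± 0.63) of the Notch pathway. Others were ENAH (1.30 ± 0.40) and ARPC2 (-1.199 ± 0.27) of the actin list, and GJA5 (-7.13 ± 0.85) and AFDN (1.13 ± 0.21) of the junction list. Of the other genes fixed by name, CYP19A1, the aromatase (1.73 ± 0.66, adjusted p = 0.037), and MYO10 (0.66 ± 0.25, adjusted p = 0.034) rose. FSHR (0.09 ± 0.46), AMH (0.80 ± 0.58), GJA1 (0.54 ± 0.28), FSCN1 (-0.07 ± 0.89), CDH1 (0.43 ± 0.66) and CDH2 (0.56 ± 0.25) were not called. The stromal protease FAP, with 0 counts in late_CC, was at least 52.0-fold lower there, counted over the group. With these genes moved summed blood cell markers (62.6 ± 33.2 against 6.69 ± 2.31 CPM in late_CC and early_CC) and endothelial markers (8.35 ± 2.48 against 21.8 ± 6.47 CPM). So did the mitochondrial share (16.7 ± 6.39% against 6.21 ± 0.759%) and the share of the 10 most abundant genes (23.3 ± 4.70% against 10.3 ± 0.698%). Each of these 4 had adjusted p = 0.0381 in exact two-sided permutation tests, and the total count, lower in late_CC, had 0.0476. The rise of the blood cell markers was that of the globins HBA and HBA1, since without these the sum was 6.94 ± 2.24 in late_CC and 6.545 ± 2.27 CPM in early_CC.

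In late_CC against early_CC the call of CYP19A1 was lost without early_CC 1, 2, 3 or 5 or late_CC 2, 4 or 5 (adjusted p = 0.0561 to 0.0751), without filtering (0.0765) and with length-corrected offsets (1.21, 0.155). That of MYO10 was lost without early_CC 1, 4 or 5 or late_CC 2 or 4 (0.0597 to 0.106), without filtering (0.0625), with the 2 groups alone (0.0553) and with length-corrected offsets (0.04, 0.894). CDH2 was called without early_CC 4 (0.69, 0.0364) or late_CC 1 (0.73, 0.0221). Without late_CC 3, which held 5.95 CPM of NDUFA4L2 and 27.7% mitochondrial counts, the glycolysis list was called higher (0.0185), as were blood cell markers (0.0419). With late_CC 3 the glycolysis list had 0.35, and 5 of 18 rose and 2 fell (5 and 1 adjusted over the list alone). AMH and GJA1 were called higher with limma-voom (1.002, 0.0173 and 0.53, 0.024) and with the 2 groups alone (0.76, 0.0374 and 0.50, 0.0382), and AMH also without the 3 libraries that stand apart (1.01, 0.000672). CDH2 was called with limma-voom (0.39, 0.0483) and over genes of at least 10 CPM (0.64, 0.0361).

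Within early antral follicles, 11 of 18 glycolysis genes were higher in cumulus than in mural cells, and the adhesion receptor VCAM1 was lower. NDUFA4L2 stood at 90.0 ± 48.9 CPM in early_CC and 1.14 ± 0.963 in early_MGC (6.18 ± 1.04, adjusted p = 0.00099). The lactate exporter SLC16A3 stood at 46.3 ± 9.59 against 3.63 ± 2.46 CPM (3.55 ± 0.69, adjusted p = 0.0025). HSD3B1 (2.44 ± 0.46, adjusted p = 0.0017) and CYP11A1 (1.96 ± 0.40, adjusted p = 0.0027) were higher in cumulus cells too. VCAM1 was lower, at 0.589 ± 0.202 against 38.8 ± 32.8 CPM (-6.11 ± 1.12, adjusted p = 0.0017). So was MSMB (ENSBTAG00000011660, chromosome 28, 44061316 to 44071826), at 1.28 ± 0.190 against 37.2 ± 34.5 CPM (-4.91 ± 0.57, adjusted p = 1.8e-05). The test called 1871 genes, 958 higher and 913 lower in early_CC, of which 467 and 532 differed at least 2-fold.

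WFDC2 (4.05 ± 0.99), HBZ (3.92 ± 0.97, from 7 counts in early_MGC), MEP1B (3.54 ± 0.83) and GUCA1A (3.47 ± 0.79), an activator of guanylate cyclase, completed the largest differences towards cumulus cells. H2AC13 (-3.72 ± 0.43), ZFP36L1 (-3.24 ± 0.54), the mitochondrially encoded ATP8 (-3.03 ± 0.56) and MSL2 (-2.79 ± 0.35) completed those towards mural cells. Glycolysis genes were higher in cumulus cells (11 of 18, none lower; 13 higher and 1 lower adjusted over the list alone; adjusted p = 7.7e-10), among them ENO1 (2.55 ± 0.41) and PGK1 (1.87 ± 0.32). The adjusted p = 0.74 with an estimated correlation. Granulosa maturation genes (5 of 24 higher and 1 lower, 8 and 1 adjusted over the list alone, adjusted p = 0.0024) had adjusted p = 0.74 with an estimated correlation, and their lower member was IGFBP2 (-3.85 ± 0.89). Cell cycle genes were higher (3 of 29, 2 adjusted over the list alone, none lower, adjusted p = 0.00085), and their adjusted p = 0.83 with an estimated correlation. Among them were the kinases AURKA (1.37 ± 0.30) and PLK1 (1.35 ± 0.36). Cholesterol genes were higher (4 of 22, the same adjusted over the list alone, none lower, adjusted p = 0.010), and for them the adjusted p = 0.83 with an estimated correlation, with MVK at 1.70 ± 0.36. From uncalled lists the junction protein AFDN (0.93 ± 0.20) and the Notch target HEY1 (3.60 ± 0.96) were higher. Lower were NECTIN3 (-1.14 ± 0.23), the co-receptor TGFBR3 (-1.78 ± 0.38), SESN1 (-1.42 ± 0.26) and the smooth muscle myosin MYH11 (-2.42 ± 0.50). Again none of the 10 tested genes fixed by name was called. MYO10 stood at 0.27 ± 0.25, FSCN1 at -0.85 ± 0.89, DAAM1 at -0.21 ± 0.29, GJA1 at -0.45 ± 0.28, GJA4 at -0.01 ± 0.93, CDH1 at 1.25 ± 0.68, CDH2 at -0.03 ± 0.25, FSHR at 0.28 ± 0.46, CYP19A1 at -0.36 ± 0.65 and AMH at 0.77 ± 0.58. The mitochondrial share was 6.21 ± 0.759% in early_CC and 20.7 ± 9.58% in early_MGC, and that of the 10 most abundant genes 10.3 ± 0.698% and 21.95 ± 8.12% (exact two-sided permutation tests, adjusted p = 0.0381 each). Summed blood cell markers stood at 6.69 ± 2.31 against 18.6 ± 10.1 CPM, and total counts were higher in early_CC (exact tests, adjusted p = 0.0476 each).

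Without early_MGC 5 the count of early_CC against early_MGC was 1222, and it was 3265 with limma-voom and 3035 with the 2 groups alone. Without the 3 libraries that stand apart CDH1 (1.26, adjusted p = 0.00106) and AMH (0.71, 0.0344) were called, as with the 2 groups alone (1.22, 0.00194 and 0.73, 0.0054) and, for CDH1, with limma-voom (1.17, 0.0101), a fit in which HBZ was not called (0.126).

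Between the cell types of late antral follicles 14 of 18 glycolysis genes were higher and 25 of 29 cell cycle genes lower in cumulus cells. NDUFA4L2 stood at 593 ± 344 CPM in late_CC and 0.726 ± 0.652 in late_MGC (9.41 ± 1.18, adjusted p = 3.4e-06). VEGFA, which drives vessel growth (ENSBTAG00000005339, chromosome 23, 17281915 to 17297193), stood at 991 ± 538 against 8.03 ± 3.09 CPM (6.67 ± 0.59, adjusted p = 3.9e-08). HBZ stood at 87.7 ± 57.3 against 0.0803 ± 0.0738 CPM (9.62 ± 0.93, adjusted p = 1.1e-07). MYO10 was higher in late_CC, at 85.6 ± 13.9 against 18.7 ± 6.21 CPM (2.01 ± 0.26, adjusted p = 1.5e-06). The test called 5673 genes, 2704 higher and 2969 lower in late_CC, of which 1806 and 1939 differed at least 2-fold.

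The muscle actin ACTA1 (7.14 ± 0.70), WFDC2 (7.07 ± 1.33) and NRXN2 (6.57 ± 0.82) were also among the 6 largest differences towards late_CC. Towards late_MGC these were the kinase SGK1 (-8.07 ± 1.77), MSMB (-6.70 ± 0.70), DCN (-6.23 ± 1.45), the receptor AXL (-6.06 ± 1.24), the G protein subunit GNG2 (-5.34 ± 1.18) and the surface protein CD99 (-5.25 ± 0.72). Of 18 glycolysis genes 14 were higher in late_CC and 2 lower, the same adjusted over the list alone (adjusted p = 1.3e-05), including HK2 (3.11 ± 0.38) and ALDOC (3.04 ± 0.38). The adjusted p = 0.74 with an estimated correlation. Of 29 cell cycle genes 25 were lower and 1 higher, the same adjusted over the list alone (adjusted p = 3.4e-09), with the spindle factor TPX2 at -2.13 ± 0.29 and the cyclin CCNA2 at -2.50 ± 0.34. Here too the adjusted p = 0.74 with an estimated correlation. Granulosa maturation genes were higher (9 of 24, 2 lower; 10 and 2 adjusted over the list alone; adjusted p = 0.042), and their adjusted p = 0.79 with an estimated correlation. GATA4 stood at 1.37 ± 0.24 and FDX1 at -0.57 ± 0.17. Of 22 actin protrusion genes 2 were higher and 9 lower (4 and 10 adjusted over the list alone), without a call of the list. The junction list was not called either, and of its 15 genes 3 were higher and 4 lower, the same adjusted over the list alone. From the lists without a call, PTGES (3.69 ± 0.59), EGFR (1.66 ± 0.30), DLL4 (3.84 ± 0.53), AFDN (1.76 ± 0.21) and the oocyte gene OOEP (1.75 ± 0.36) were higher in late_CC. GREM1 (-1.29 ± 0.23), ID1 (-3.73 ± 0.65), GJC1 (-1.69 ± 0.33) and EZR (-0.96 ± 0.21) were lower. Of the remaining genes fixed by name, AMH (1.55 ± 0.59, adjusted p = 0.039) was higher and GJA1 (-0.73 ± 0.28, adjusted p = 0.044) and GJA4 (-4.01 ± 1.18, adjusted p = 0.0095) lower. FSHR (0.17 ± 0.46), CYP19A1 (0.73 ± 0.64), FSCN1 (-1.59 ± 0.90), DAAM1 (0.69 ± 0.29), CDH1 (-0.78 ± 0.66) and CDH2 (0.52 ± 0.25) were not called. Summed blood cell markers stood at 62.6 ± 33.2 CPM in late_CC and 7.79 ± 8.83 in late_MGC (exact two-sided permutation test, adjusted p = 0.0476), but at 6.94 ± 2.24 and 7.63 ± 8.56 without HBA and HBA1. Library late_MGC 3 held 23.4 CPM of these markers, HBA and HBA1 included, and the other late_MGC libraries at most 5.62. The late_MGC means therefore lean on 1 library, and the 2 means without HBA and HBA1 do not show equal levels. Oocyte markers stood at 13.3 ± 4.17 against 4.44 ± 1.22 CPM (exact test, adjusted p = 0.0381).

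Without late_MGC 3, SGK1, DCN, AXL and GNG2 stood at -1.65, -2.12, -2.58 and -1.51, GJA4 was not called (-0.53, adjusted p = 0.635). FSCN1 (1.77, 0.0068), CDH1 (1.498, 5.6e-05), DAAM1 (1.15, 0.000409) and CDH2 (0.76, 0.013) were then called higher in late_CC. The granulosa maturation list lost its call without late_CC 1, 4 or 5 or late_MGC 3 (0.0597, 0.0718, 0.0729 and 0.108). AMH was not called without late_CC 2, 4 or 5 or late_MGC 1 or 4 (0.0526 to 0.0802), without filtering (0.0815) or with the 2 groups alone (0.138). GJA1 was not called without any library but late_CC 3 or late_MGC 3 (0.0576 to 0.106), over genes of at least 10 CPM (0.0789) or with the 2 groups alone (0.0854). Without late_CC 1, DAAM1 (0.80, 0.0441) and CDH2 (0.67, 0.0387) were called higher in late_CC. So they were with limma-voom (0.98, 2.7e-05 and 0.50, 0.00968) and over genes of at least 10 CPM (0.79, 0.0351 and 0.63, 0.0432). With limma-voom, DCN (-2.59, 0.144) and GJA4 (-2.46, 0.0678) were not called. There CDH1 (1.201, 0.000406) and FSCN1 (2.22, 0.00279) were called higher in late_CC. Without the 3 libraries that stand apart CYP19A1 was called (0.69, 0.0158), and DCN and GJA4 were not (0.0979 and 0.0987).

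**Figure D3:**
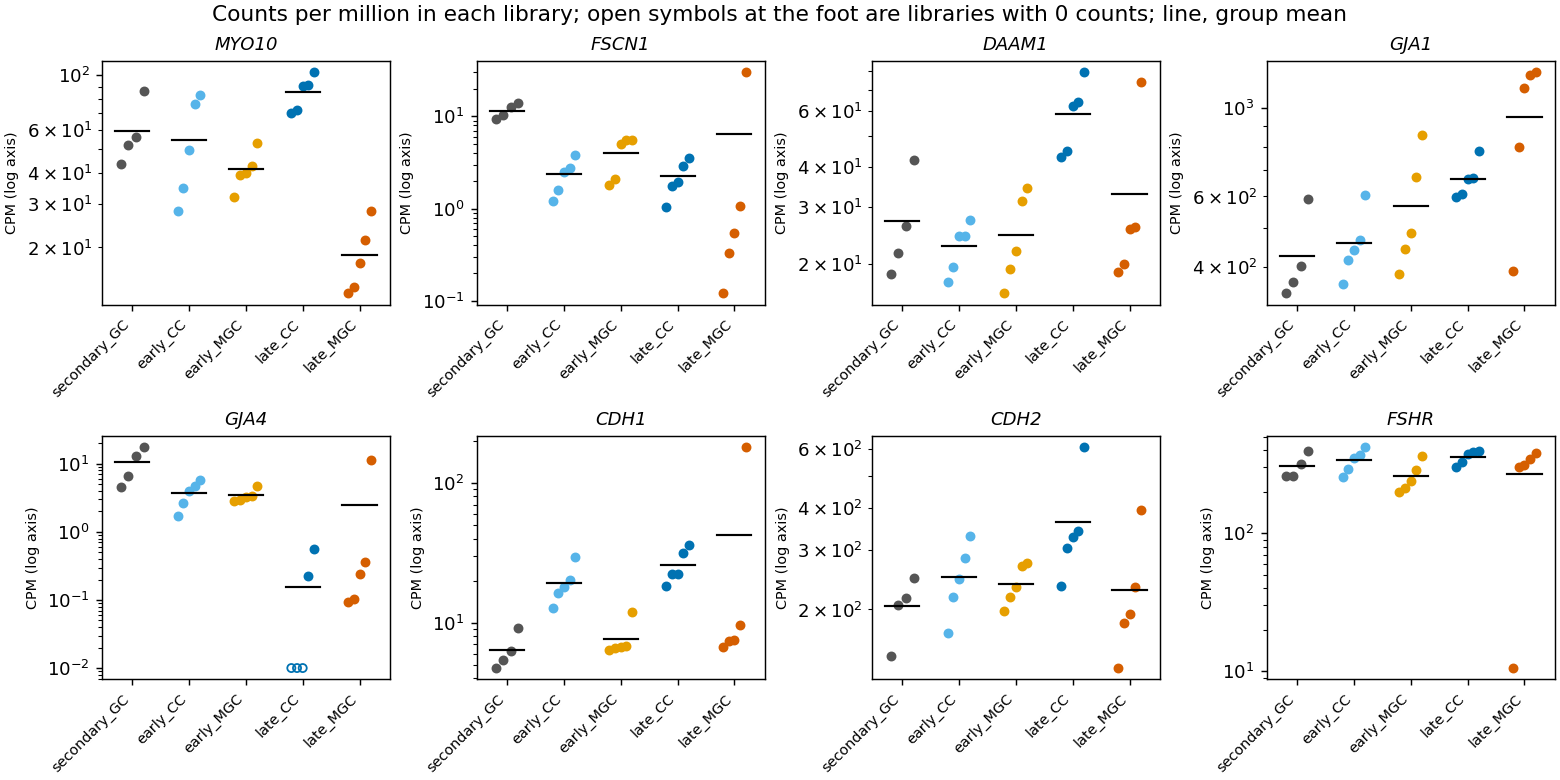
CPM of 7 genes of cell contact and protrusions and of FSHR in each of the 24 libraries on log axes, with a line at each group mean and open symbols for libraries with 0 counts. FSCN1 averaged 11.5 CPM in secondary_GC and 2.23 to 6.45 CPM in the antral groups, where 1 late_MGC library held 30.2 CPM, and MYO10 averaged 85.6 CPM in late_CC and 18.7 CPM in late_MGC.

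The change from early to late antral follicles differed between cumulus and mural cells for 4486 genes, 2074 with a larger log2 value in cumulus cells and 2412 with a smaller one. HBZ (5.70 ± 1.87), the nuclear receptor NR4A1 (4.49 ± 0.83), ZFP36L1 (4.39 ± 0.73) and the glycolytic regulator PFKFB3 (4.38 ± 0.57) had the largest positive interaction. The muscle protein CSRP3 (-10.65 ± 2.75), DCN (-6.07 ± 1.77), SGK1 (-5.84 ± 2.1) and CD99 (-5.75 ± 0.91) had the largest negative. MYO10 (1.74 ± 0.36, adjusted p = 0.00069) and GJA4 (-4.01 ± 1.49, adjusted p = 0.045) were the only genes fixed by name with a call. FSHR (-0.12 ± 0.65), CYP19A1 (1.09 ± 0.91), AMH (0.79 ± 0.81), GJA1 (-0.28 ± 0.40), FSCN1 (-0.74 ± 1.25), DAAM1 (0.90 ± 0.41), CDH1 (-2.03 ± 0.95) and CDH2 (0.56 ± 0.35) had none. Without late_MGC 3 the interaction was -2.25 for CSRP3 (adjusted p = 0.220), -1.96 for DCN (0.147), 0.57 for SGK1 (0.602) and -0.53 for GJA4 (0.702), none of them called. CSRP3 lost its call in no other alternative that tested it. DAAM1 (1.37, 0.00198) and FSCN1 (2.62, 0.00325) were called there, and FSCN1 with limma-voom (2.75, 0.00308). Without the 3 libraries that stand apart CYP19A1 (1.14, 0.00642) and GJA1 (-0.87, 0.0227) were called as well. The call of HBZ was lost without early_MGC 1 (5.26, 0.0949) or 2 (4.86, 0.171) and with limma-voom (0.0713). SGK1 was also not called without early_CC 2 or 3, any early_MGC library but 3 or any late_CC library (0.0531 to 0.0656). GJA4 was not called without early_CC 2, 4 or 5, early_MGC 1, 2, 3 or 5 or late_CC 1, 2, 4 or 5 (from 0.0574). DCN, SGK1 and GJA4 were not called with limma-voom (0.264, 0.717 and 0.0841). Without filtering and with the 4 antral groups alone SGK1 (0.0567 and 0.0502) and GJA4 (0.0681 and 0.0585) were not called, nor GJA4 with length-corrected offsets (0.0752), and DAAM1 was called with limma-voom (1.098, 0.00167).

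Genes highest or lowest in early_MGC among the mural and secondary stages were taken because the study uses these cells as its reference for projection growth. GREM1 was the foremost of 81 genes higher in early_MGC than in both secondary_GC and late_MGC (2.24 ± 0.25 against secondary_GC, and -2.33 ± 0.23 for late_MGC against early_MGC). It was followed by USP27X (1.68 ± 0.29 and -2.23 ± 0.27), NUDT11 (1.30 ± 0.35 and -2.25 ± 0.33), the imprinted gene PEG3 (1.23 ± 0.31 and -3.28 ± 0.31) and the glycosyltransferase GALNT13 (1.54 ± 0.35 and -1.202 ± 0.32). CYP11A1 led 86 genes lowest in early_MGC (-1.96 ± 0.41 and 3.25 ± 0.42). With it came HES1 (-1.85 ± 0.45 and 1.78 ± 0.43), ERRFI1 (-1.71 ± 0.54 and 1.99 ± 0.52), PLA2G7 (-1.70 ± 0.45 and 1.64 ± 0.43), the collagen COL6A2 (-1.39 ± 0.32 and 2.13 ± 0.31) and the nucleoside transporter SLC29A1 (-1.21 ± 0.24 and 2.69 ± 0.24). Independent lists of these sizes would share 66.7 and 57.0 genes. Simulated unchanged groups that share the early_MGC libraries shared 0 in each of 20 runs. Since no gene changed in them, they set no expectation for lists of changed genes. The 10 splits of the early_MGC libraries between the 2 comparisons shared 8 to 22 and 2 to 16 genes. Their medians were 10.5 and 6, against medians of 11.2 and 3.59 expected of independent lists. Genes highest in early_MGC thus showed no excess in the splits. The total of 167 was 280 without late_MGC 3, and 92, 108, 70, 82 and 102 without secondary_GC 1, 2 or 4 or early_MGC 4 or 5. It was 60 for at least a doubling or halving, 254 with DESeq2, 89 without filtering and 251 without the 3 libraries that stand apart. A call against secondary_GC was lost without secondary_GC 4 for HES1 (0.0521) and without early_MGC 5 for NUDT11 (0.0557). It was also lost without secondary_GC 2 or 4 or early_MGC 5 for PEG3 (0.0551 to 0.0711), without secondary_GC 1 or 4 or early_MGC 5 for PLA2G7 (0.0502 to 0.0641) and without any library but secondary_GC 1 or 3 for ERRFI1 (0.0663 to 0.155). Without late_MGC 3 the rise of ERRFI1 in late_MGC was 0.86 and not called (0.0536), and that of HES1 was 1 (0.0194). With the 2 groups alone the rises of HES1, ERRFI1 and PLA2G7 in late_MGC were not called (0.0647, 0.0621 and 0.0727), nor that of HES1 with limma-voom (0.86, 0.0784). NUDT11 and PLA2G7 were not called against secondary_GC with the 2 groups alone (0.055 and 0.0759), nor ERRFI1 without filtering (0.0897).

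Late antral calls overlapped between the cell types. NKD1, GREM1, ID1, HEYL, AMHR2 and GJA5 fell and CYP11A1, HES1 and CTNNB1 rose in both. The rise of HES1 in late_MGC was not called with limma-voom (0.0784) or with the 2 groups alone (0.0647), nor that of CTNNB1 in late_CC with length-corrected offsets (0.44, 0.0725). In all, 472 genes were higher in both and 568 lower in both, where independent lists would share 313 and 302. In 447 genes the directions were opposite, MYO10 among them, where independent lists would give 615. The rise of MYO10 in late_CC lost its call in 8 alternatives, and was 0.04 (0.894) with length-corrected offsets. Across genes, which are not independent replicates, the log2 changes of the 2 cell types had a Pearson r of 0.37 and a Spearman correlation of 0.16. At least a doubling or halving left 658 of the 1040 genes with a shared direction.

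The actin protrusion list and the junction list, the gene groups closest to transzonal projections, were called in 0 of 12 camera tests (adjusted p = 0.42 to 0.94, unadjusted 0.18 to 0.90), and in none with an estimated correlation. Lists of cumulus expansion (adjusted p = 0.13 to 0.88), basement membrane (0.098 to 0.88), apoptosis and p53 response (0.63 to 0.97), oocyte markers (0.36 to 0.93), theca and stroma markers (0.88 to 0.95) and endothelial markers (0.090 to 0.97) were not called in any comparison either. The signs of median and test differed in uncalled lists only, such as the actin list in early_MGC against secondary_GC (median -0.01, test higher) and the apoptosis list in late_MGC against early_MGC (median 0.63, test lower), and the junction list in late_CC against late_MGC had a median of 0.02 and a mean of -0.46. Leaving out 1 library called the basement membrane list in late_MGC against early_MGC (0.0307 without late_MGC 3) and, in early_CC against secondary_GC, the endothelial markers (0.0298 without early_CC 5), the granulosa maturation list (0.0199 without secondary_GC 2) and the Notch list (0.0424 without early_CC 3). Of all 102 tests 21 were called with the preset correlation and 0 with an estimated one.

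**Figure D4:**
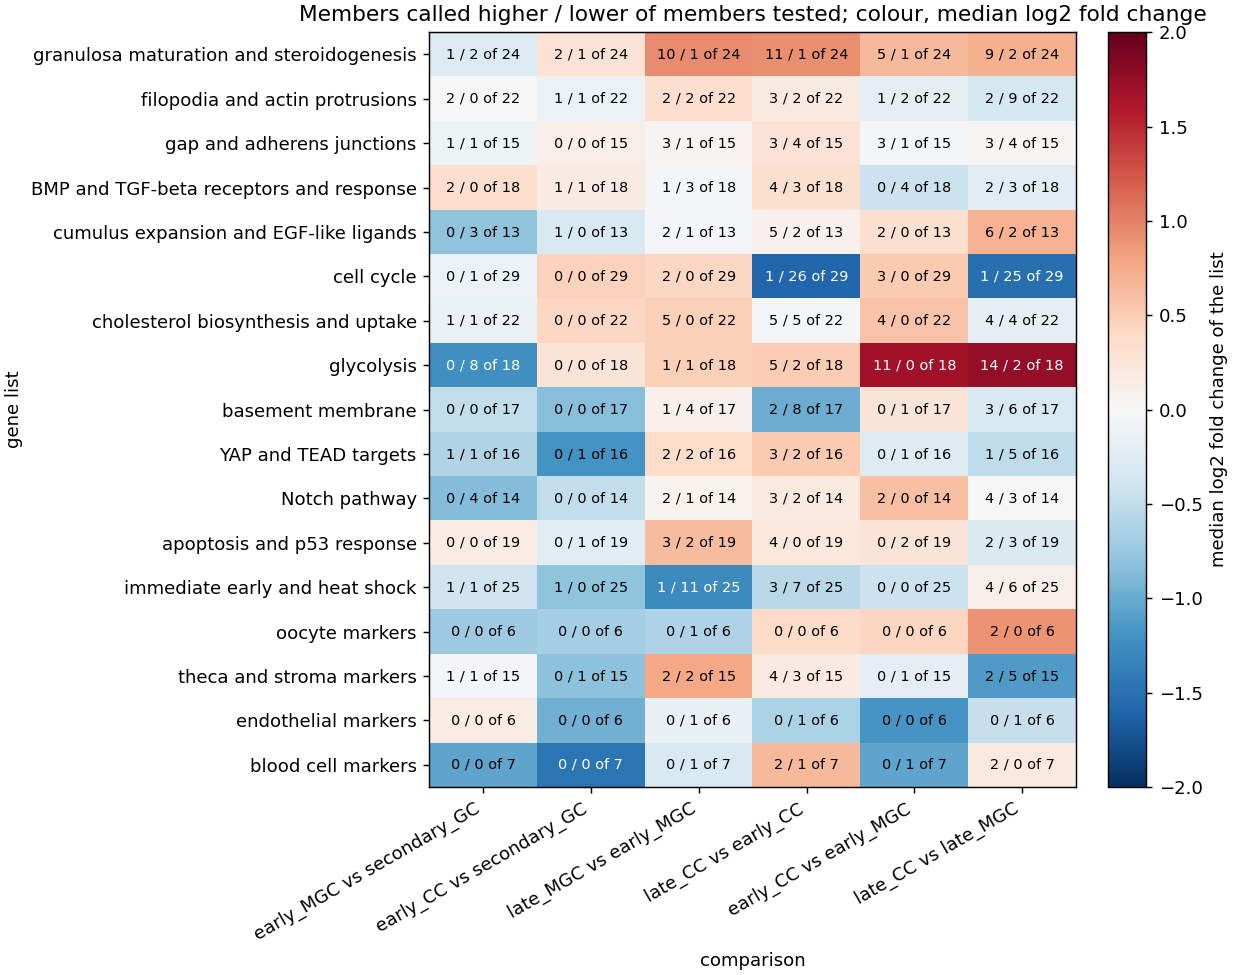
Median log2 fold change of each of the 17 gene lists in the 6 comparisons as colour, with the members called higher and lower and the members tested in each cell. In late_CC, 26 of 29 cell cycle genes were lower than in early_CC and 14 of 18 glycolysis genes higher than in late_MGC.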

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

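Of the tests in this part, those of depth, of theca or stroma cells, of red blood cells, of the length trend as the whole source of calls and of the length slopes of single libraries were chosen only after the result was seen, as was the fit with length-corrected offsets.

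Single libraries stood far from the rest of their group by Dixon's test in 22 of 130 groups of values, where chance alone gives about 1 in 20 groups, or 6.5. Library late_MGC 3 accounted for 11 of them: it was highest for summed theca and stroma markers (2827 CPM), endothelial markers (28.2), blood cell markers (23.4), GJA4 (11.5), FSCN1 (30.2), DAAM1 (74.0), CDH1 (181), HBA (0.375), CYP11A1 (249.6) and HSD3B1 (306), and lowest for FSHR (10.6). Library late_CC 3 had the highest mitochondrial share (27.7%), LHCGR (0.415 CPM) and CDH2 (609.6 CPM) and the lowest HSD3B1 (39.5 CPM) of its group. The others were late_CC 1 for oocyte markers (20.7 CPM), early_CC 1 for theca and stroma markers (902), early_CC 4 for LHCGR (0.345), early_MGC 4 for GJA4 (4.77), early_MGC 5 for CDH1 (11.8) and HBA (0.186), and secondary_GC 2 for VEGFA (117), each the highest of its group.

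The change from early to late antral follicles differed between cumulus and mural cells in 4486 genes by the tested interaction. The named genes among them were HBZ (5.70), NR4A1 (4.49), ZFP36L1 (4.39), PFKFB3 (4.38), MYO10 (1.74), CSRP3 (-10.65), DCN (-6.07), SGK1 (-5.84), CD99 (-5.75) and GJA4 (-4.01). Without late_MGC 3 the interaction was -2.25 for CSRP3, -1.96 for DCN, 0.57 for SGK1 and -0.53 for GJA4. CSRP3 kept its call under every other alternative that tested it. The interaction of HBZ was not called without early_MGC 1 or 2 (5.26 and 4.86), nor were those of SGK1 and GJA4 without most other libraries, as named in the report. The column of reads that belong to no sample held 8.3% of all counts in the table.

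Library late_MGC 3 held little of the granulosa transcripts FSHR (10.6 against a mean of 335 CPM in the other 4 libraries), AMH (2.73 against 210.3), HSD17B1 (8.25 against 922) and INHA (26.3 against 2263), and much of ANKRD1 (2029 against 1.19), CSRP3 (1971 against 1.1), LUM (1621 against 12.2), STAR (123 against 3.12) and DCN (276 against 2.90). Not all genes of granulosa cells were low in it. HSD3B1 (306 against 99.9 CPM), CYP11A1 (249.6 against 91.5) and CDH2 (394 against 186) were higher than in the other 4. GATA4 (50.3 against 75.7) and NR5A2 (239 against 492) were lower to a lesser degree. Low depth is argued against, since 2 of the other 4 libraries had a lower total count. A swap with a library of another group is argued against as well, because 0 libraries of other groups correlated more closely with the other 4 late_MGC libraries than with their own group. Theca or stroma cells in place of granulosa cells stay open, because the values go both ways. On the low side, the highest of CYP17A1, COL1A1 and COL1A2, abundant transcripts of such cells, was 8.302 CPM. INSL3, the most abundant member of the theca and stroma list, stood at 1.88 against 270.6 CPM in the other 4 libraries. CYP17A1 had 0 CPM in those 4, so INSL3 was high without it and its low level cannot speak against theca cells. On the high side, COL3A1 stood at 49.4 against 0.237 CPM, and LUM and DCN were high. A single wrong label or a sample from outside the groups may be the source too. Its mean correlation was highest with its own group (0.870), with early_MGC next (0.857). It shares the well letter C with late_CC 3, which also stands apart. With group means removed, these 2 libraries correlated at 0.28, against a mean of -0.15 for late_CC 3 with the other letters. What a shared letter means is not stated. No other biological explanation was tested, since the labels put late_MGC 3 in no group of its own.

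Glycolysis genes (14 of 18 higher) and the globins HBZ and HBA (7421 and 3670 counts) were high in late_CC against late_MGC. Library late_CC 3 held less of the blood cell markers, which include HBA. Their sum was 11.97 CPM there and 46.9 to 90.7 in the other late_CC libraries, and NDUFA4L2 was low in it too. Red blood cells stay open. The adult beta globin HBB, which they hold in amounts like those of alpha globin, had 0 counts in late_CC. It was at most 0.08174% of HBA there, counted over the group. But HBB also had 0 counts in all other groups, so it may not be countable in these data and its absence cannot decide. The length trend of the libraries is argued against for the glycolysis list, which had adjusted p = 3.466e-06 with length-corrected offsets, a value that rests on the preset correlation. A wider set of targets of the hypoxia-inducible factor, a list not among the 17 fixed beforehand, moved with it. Of its 25 tested members 76% were higher and 1 lower (median 2.25, camera adjusted p = 4.2e-12, and 0.27 as adjusted p with an estimated correlation). A lower oxygen supply of late cumulus cells in the follicle or after collection may underlie this, and the design cannot part these from a difference between the cell types.

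Fold changes of late_CC against late_MGC rose with exon length, with a Spearman correlation of 0.23 across genes, and of 0.28 for late_CC against early_CC. Short genes of translation and oxidative phosphorylation alone are argued against as the source, since the correlation was 0.2114 without them, and so is the trend as the whole source of the calls, since 5429 genes were called with length-corrected offsets, 4551 of them shared with the 5673. The slopes of the libraries come from the same counts as the trend, so they show only that it was not carried by single libraries. They lay between 0.0907 and 0.315 in late_CC, above every one of late_MGC (at most 0.0854, exact two-sided permutation p = 0.007937) and of early_CC (-0.271 to -0.120), with 0.0238 as adjusted p for both. This leaves open any property that follows the groups. RNA integrity or handling that followed the groups and a biological shift towards long transcripts may each be the source, and the labels give no batch to test them.

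Other splits of the libraries were drawn, 100 per result with the real one included. For the 6 comparisons they argue against chance as the source of the counts, provided the samples are independent, which the labels do not say. For the interaction the splits exchanged cell types within a stage, and for the late overlap stages within a cell type. Those splits therefore cannot test the interaction or the sharing apart from these effects. As many genes as the real split came from 1 split, the real one, for early_MGC against secondary_GC (1301, highest other 85), early_CC against secondary_GC (285 and 21), late_MGC against early_MGC (2725 and 1256), late_CC against early_CC (6457 and 1351), early_CC against early_MGC (1871 and 1), late_CC against late_MGC (5673 and 2853), the interaction (4486 and 2761) and the late overlap (1040 and 0). For genes highest or lowest in early_MGC 3 splits gave as many as the real 167, and the highest other gave 454, several times as many, which points to a structure of the samples. That split put the 4 late_MGC libraries other than late_MGC 3 in place of early_MGC, and so set late_MGC against a mix of the groups.

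For the gene lists chance is not excluded in any comparison. As many lists called, adjusted over the 17 of a comparison, came from 71 splits for early_MGC against secondary_GC (real 1, highest other 6). They came from 53 for late_MGC against early_MGC (4 and 12) and 76 for late_CC against early_CC (2 and 7). For early_CC against early_MGC there were 22 (4 and 8), and for late_CC against late_MGC 73 (3 and 11). The fewest were 2, for early_CC against secondary_GC (7 and 8). A smallest list p as small came, in the order of the comparisons, from 7 splits (real 1.3e-10, smallest other 4.9e-15), 15 (1.9e-05 and 9.3e-11), 65 (3.5e-05 and 9.2e-26), 12 (9.7e-11 and 8.3e-16), 4 (7.5e-12 and 1.1e-14) and 43 (1.2e-10 and 9.7e-29). The fewest were 4, for early_CC against early_MGC. A split other than the real one reached a smaller p in every comparison, and these split tests were not adjusted for their number.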

How the results depend on the processing

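The fits without the 3 libraries that stand apart, with length-corrected offsets and with the well letter as a block were chosen only after the results were seen. The counts of late_CC against early_CC, late_CC against late_MGC and the interaction stayed within 1.5 times their values under every alternative run, the interaction between 3826 and 5138 with 1 library left out. Of 285 genes in early_CC against secondary_GC the count was 722 with DESeq2 (284 shared), 148 over genes of at least 10 CPM (143 shared), 812 with limma-voom (250), 964 with the 2 groups alone (262), 1304 without the 3 libraries (285), 432 with length-corrected offsets (278) and 150 to 358 with 1 library left out. That of late_MGC against early_MGC, 2725, was 1608 over genes of at least 10 CPM (1469 shared), 4756 with limma-voom (2543) and 1612 with the 2 groups alone (1550), and that of early_CC against early_MGC, 1871, was 3265 with limma-voom (1816), 3035 with the 2 groups alone (1779) and 1222 to 1761 with 1 library left out. That of early_MGC against secondary_GC, 1301, was 516 to 1524 with 1 library left out. Fewer genes tested and fewer samples explain part of the smaller counts, and the cause of the other shifts was not tested.

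The 167 genes highest or lowest in early_MGC became 60 with at least a doubling or halving, which is narrower by construction, 254 with DESeq2, 89 without filtering, 251 without the 3 libraries and 70 to 280 with 1 library left out, and the 1040 of the late overlap became 658 with at least a doubling or halving. The 21 list calls became 0 with an estimated correlation, and the cause was not tested. Of the list tests with 1 library left out 952 stayed called or uncalled, 28 lost and 6 gained a call. Without the 3 libraries 8 gained a call, and with length-corrected offsets 2 lost and 2 gained one.

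Of 320 called values of named genes 219 kept their call under every alternative fixed beforehand that was run and tested the gene, which in 111 cases it did not. Directions turned for JAG1 in late_MGC against early_MGC (-1.89 with limma-voom, -1.54 without the 3 libraries, -1.69 to 4.57 with 1 left out), FSCN1 there (-2.94, -2.51, -2.69 to 0.98), FSCN1 in late_CC against late_MGC (2.22, 1.49, -1.91 to 1.77), STAR there (0.29, 0.42, -2.83 to 0.44), CDH1 there (1.201, 1.31, -1.05 to 1.498), FSCN1 in the interaction (2.75, 2.17, -1.05 to 2.62) and SGK1 in the interaction (0.60 without the 3 libraries, -6.16 to 0.57). Each of these turned with late_MGC 3 left out; the cause was not tested.

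With the replicate number as a block, late_CC against early_CC gave 6185 genes (5996 shared) and early_CC against early_MGC 1579 (1518 shared). No list call changed, and 6 of 69 and 2 of 39 calls of named genes were lost, that of CYP19A1 in late_CC against early_CC among them (1.48, adjusted p = 0.123). The columns of secondary_GC and late_MGC lack the numbers of the labels, so for the other results the block was the well letter in the column name, which follows the number in the other groups. It gave 1033 genes in early_MGC against secondary_GC (905 shared), 157 in early_CC against secondary_GC (142), 2645 in late_MGC against early_MGC (2392), 5927 in late_CC against late_MGC (5373) and 4515 in the interaction (4068). The Notch list of early_MGC against secondary_GC was not called (0.0571), JAG1 in late_MGC against early_MGC turned to -0.78, and 36 named values lost and 6 gained a call. Lost among the genes of the report were NDUFA4L2 (-4.23, adjusted p = 0.0549), IER3 (0.0626) and ERRFI1 (0.149) in early_MGC against secondary_GC, and WFDC2 (0.099), TMEM156 (0.0514), VCAM1 (0.127), IFRD1 (0.206) and IGFBP6 (0.11) in early_CC against secondary_GC, where 13 of 24 named calls were lost. The others were CDH1 (0.87, 0.244) and ERRFI1 (0.0565) in late_MGC against early_MGC, GJA1 (-0.64, 0.0941) in late_CC against late_MGC, and DCN (0.112) and SGK1 (0.524) in the interaction. The 6 gained were GJA4 in late_MGC against early_MGC (-3.03, 0.0312), CYP19A1, DAAM1 and CDH2 in late_CC against late_MGC (1.14, 0.81 and 0.49) and CYP19A1 and DAAM1 in the interaction (1.47 and 1.005). After the group means were removed, libraries of the same number correlated at -0.06 to 0.20 and -0.10 to 0.24, and those of the same letter at -0.17 to 0.41, so in no comparison did every pair correlate at over 0.1 and the samples were not taken as paired. Over 0.1 were 3 of the 5 letter pairs of late_CC and late_MGC and 3 of the 4 of early_CC and secondary_GC. All 5 late_CC libraries correlated best with the late_MGC library of their own letter (0.05 to 0.41), so pairing stays possible there, as a hint from the data, not the design. The quality tests gave 17 calls in place of 16 with TMM-scaled CPM. Depth sets the limit below which a gene is not seen, such as 0.0402 CPM for LHCGR in secondary_GC. Simulated data at these depths, in which few genes changed, recovered 24% to 38% of genes changed 2-fold. How far depth, spread or the small number of changed genes held this down was not tested.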

Other observations

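The family tests in this part were all chosen only after the result was seen.

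Of 76 nuclear genes of the respiratory chain 72 were lower in late_CC than in late_MGC and 1 higher (median -1.57, 67 lower and 2 higher with length-corrected offsets, camera adjusted p = 5.0e-43 over the 48 family tests, and 0.25 as adjusted p with an estimated correlation). Against early_CC 69 fell and 0 rose (median -1.21). Of 71 mitochondrial ribosomal proteins 58 were lower in late_CC than in late_MGC and 3 higher, and of 37 proteasome genes 23 were lower and 0 higher. These counts and those against early_CC are not corrected for the trend with exon length. That trend had a Spearman correlation of 0.28 for late_CC against early_CC and 0.23 for late_CC against late_MGC. In late_MGC against early_MGC 31 respiratory chain genes rose and 2 fell (adjusted p = 8.0e-09, and 0.61 with an estimated correlation), and 18 of 37 proteasome genes rose and 0 fell.

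Of 27 replication histones 7 rose in early_MGC against secondary_GC and 0 fell (median 1.32, adjusted p = 8.1e-12, and 0.48 with an estimated correlation). Of 13 genes encoded in the mitochondrion 10 were lower in early_CC than in early_MGC and 0 higher (adjusted p = 1.1e-08, and 0.50 with an estimated correlation). These genes are part of the mitochondrial share, 6.21% against 20.7%, so this is no separate result.

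FSCN1 and GJA4, genes of actin bundles and of the gap junctions with the oocyte, may decline from secondary to antral follicles. Without the 3 libraries that stand apart FSCN1 was called lower than in secondary_GC in early_MGC (-1.57, adjusted p = 0.0227) and early_CC (-2.25, adjusted p = 0.0014), and GJA4 likewise (-1.65 and -1.44). With all 24 libraries, edgeR called neither, and neither gained a call with DESeq2, RLE scaling, no filter or length-corrected offsets. By contrast, limma-voom with library weights called FSCN1 (-1.63 and -2.17) and GJA4 (-1.68 and -1.58) in both. So did edgeR with the 2 groups alone (-1.40 and -2.30, and -1.43 and -1.48).

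The most abundant members of the marker lists, as means over the libraries, were OOEP, NOBOX and DAZL (11.3, 1.34 and 0.85 CPM) for oocytes, INSL3, LUM and MYH11 (202, 133 and 95.7) for theca and stroma, FLT1, TEK and CLDN5 (15.6, 1.88 and 1.82) for endothelium and CXCR4, HBA and HBA1 (9.65, 9.09 and 2.67) for blood cells. Summed theca and stroma markers differed in none of the 6 comparisons in exact permutation tests.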
